A study of Caenorhabditis elegans with 3 samples.

How the data were processed

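The samples were 3 two-colour arrays of Caenorhabditis elegans. Per the labels, channel 1 of each array held a mixed wild-type reference and channel 2 mRNA of a preparation of adult hermaphrodites, numbered 1 to 3. All 3 formed 1 group, with the preparation number as the replicate number. Each array carries a title of its own, with an array number and an ending that reads as a date, different for each preparation. Preparation, array and date therefore cannot be told apart, and no batch of more than 1 array could be tested.

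The values that the authors deposited are log2 ratios of the channels, 1 per row and array. The log base was read from the values: all 59554 values with a linear ratio under 10 lay within 0.01 of a step of a 0.001 grid once raised from base 2. The scanner, background correction, spot filter and normalisation method are not given in the sources used here. The array means were -0.0028, -0.0034 and -0.0020 and the medians 0.0129, 0.0356 and 0.0086 for replicates 1, 2 and 3, so the values as deposited were centred near 0. No dyes and no direction of the ratio are stated, and no spot intensities were used here, so dim and saturated spots could not be set apart. Compression of ratios by background or saturation would understate the changes. The table held 0 columns of no sample.

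Of the 20000 rows, 15655 had a single gene symbol in the platform annotation of 2007, 198 had several and 4147 had none. Symbols were updated through the RefSeq gene table of assembly WBcel235, used for names only, which matched 15569 rows by gene identifier and 7 by transcript accession, while 79 kept the annotation's symbol. The update changed 1 symbol. Rows of the same symbol were averaged on each array (467 symbols, 954 rows), and rows with several symbols or none were kept as they were and not named. Of 430 symbols with several tested rows, 0 had rows that passed in opposite directions. Values were missing on 96, 168 and 161 rows of replicates 1, 2 and 3. Genes with a value on all 3 arrays were tested, which left 19293 (15112 with a symbol and 4181 rows without a single one) and set aside 220.

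The log2 ratio of each gene was tested against 0 in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, without trend or robust options, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior had 5.86 degrees of freedom and an SD of 0.27, and the fit had 2 residual degrees of freedom per gene. With 3 arrays a sign-flip test cannot go below a two-sided p of 0.25, so the calls rest on the moderated variance shared across genes. The median SD of a gene over the arrays was 0.243, and the smallest absolute log2 ratio that passed was 0.42.

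There were 22 gene lists, fixed before the data were examined from general knowledge of the organism: vitellogenins, eggshell, oocyte regulators, early zygotic genes, major sperm proteins, other spermatogenesis genes, meiotic genes, P granule and germline RNA regulators, replication and cell cycle, histones, cuticle collagens, moulting genes, muscle, neurons, intestine, somatic gonad, male-specific genes, ribosomal proteins, mitochondrial genes, proteasome, glycolysis, and heat shock and stress. The 21 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes. Camera was also run with a correlation estimated per list, together with fry. "Higher" and "lower" members passed the threshold over all genes tested. Counts adjusted over the list alone are given beside them.

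The rule for named genes was set before the data were examined. It took the 10 genes with the largest positive and the 10 with the largest negative mean log2 ratio among genes with a symbol or sequence name, an adjusted p under 0.05 and the same sign on all 3 arrays. It added the 3 members of each list with the smallest p, and the leading member of the other direction where a list had members past the threshold on both sides. This gave 86 genes, of which 82 passed. Genes of other observations were chosen after their values were seen.

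The fit and list tests were tested on simulated data beforehand. In 20 draws of 19293 genes on 3 arrays against 0, with 200 genes changed, 1.6% of genes changed by a log2 ratio of 0.5 were recovered, 67.7% at 1, 99.4% at 2 and 100% at 4, and 5.69% of calls were false. These draws took the variance prior from these arrays and held independent genes without a bias by place. In the data 5501 genes passed, so the adjusted threshold was less strict there and these shares do not carry over. In 100 draws of 30 unshifted genes whose values correlated at 0.2, camera with the preset correlation gave a p under 0.05 in 36% of draws and with an estimated correlation in 1%. At a correlation of 0.6 the shares were 60% and 3%. The preset version can therefore call correlated lists that are not shifted. Lists of 30 genes shifted by 1.2, 0.8 and -1.6 with correlations of 0.1, 0.2 and 0.6 gave an unadjusted p under 0.05 in 100%, 98% and 99% of draws with an estimated correlation, and in 100% of draws with the preset one. The estimated version was thus able to call shifted lists in the simulation, with no other list shifted and no adjustment over lists. In the data 5501 genes passed, so these shares do not carry over to the lists there. Major sperm proteins, with a median of -1.64 and an estimated correlation of 0.593, gave an unadjusted camera p of 0.140. A list that did not pass with an estimated correlation is therefore not shown to be unshifted.

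The alternatives fixed beforehand were median centring, centring with scaling, values on at least 2 arrays, rows not averaged, a robust prior, array weights, no moderation, each replicate left out in turn, 2 other thresholds, and camera with an estimated correlation or on ranks. Scaling used limma's median absolute value method, which limma applies to two-colour log ratios. With missing values or a robust prior, camera was run on the fit's own statistics. Centring of stretches of 625 rows, subtraction of an 11 by 11 neighbourhood median, the list medians without each replicate, and the counts of gene classes without each replicate or with array weights were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.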

Results

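Transcript levels were measured in adult hermaphrodites of the nematode Caenorhabditis elegans on 3 two-colour DNA microarrays. On each array 1 channel held mRNA of a preparation of adults, which the labels mark TP12 and "w/ emb 3", read here as adults with embryos. The other channel held a mixed wild-type reference whose composition is not described in the labels. The 3 arrays form 1 group of 3 preparations. The labels do not say whether the preparations were separate cultures. Each preparation was on 1 array, so the spread between preparations cannot be told apart from that between arrays, and it may be technical. The p-values rest on this spread together with the variance shared across genes. Replicate 1 had 19904 measured values, replicate 2 had 19832 and replicate 3 had 19839, out of 20000 rows each. The precision is limited by the number of arrays.

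The comparison that the design gives is the adults against the mixed reference. The question it answers is which transcripts stood at another level in these adults than in the pool, relative to the centre of each array. The deposited values were centred near 0, so a difference shared by most transcripts would not be seen. The pool's own spread was not measured, since the ratio was tested against 0. The direction of the deposited ratio is not stated. It is called likely adults over reference, on the basis of the channel order in the labels and of 4 gene lists whose direction was set before the data were examined. The median log2 ratio was 1.19 for eggshell genes, 0.24 for vitellogenins, -0.33 for moulting genes and -1.64 for major sperm proteins, each on the side set beforehand. These 4 lists are therefore not independent evidence of their own direction. "Higher" and "lower" in adults rest on this likely direction throughout, and would exchange places under the opposite one.

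Most measured genes of the oocyte, eggshell, meiotic, germline RNA, DNA replication and proteasome lists were higher in the adults, and 28 of 30 major sperm protein genes were lower. Of the cuticle collagen, moulting and neuronal genes, 71 of 152, 33 of 85 and 30 of 61 were lower, with 17, 1 and 0 higher. These 10 lists passed limma's camera test with its preset correlation and none passed with an estimated correlation, where the adjusted p ran from 0.283 to 0.537. The gene with the largest negative ratio was acs-2, an acyl-CoA synthetase of fatty acid oxidation, at -5.04 ± 0.57 (SD, n = 3), or 33-fold lower. The named gene with the largest positive ratio was irg-5, an infection response gene, at 3.78 ± 1.09 (SD, n = 3), or 13.8-fold higher. In limma with Benjamini-Hochberg adjustment, 5501 of 19293 genes passed an adjusted p of 0.05, of which 2854 were higher (14.8% of those tested) and 2647 lower (13.7%). Of these, 2272 higher and 2288 lower genes carried a single gene name, and 582 and 359 were rows without one. An absolute log2 ratio of at least 1 was reached by 749 of the higher and 941 of the lower genes. The sign was the same on all 3 arrays for 57.4% of genes. The channel order and the reference were the same on all 3 arrays, so an effect of a gene's dye or of the reference would also have 1 sign on all of them. With each array centred on its median the counts were 2707 higher and 2718 lower, so their near balance depends in part on the centring. Without replicate 2 the counts were 1796 higher and 1687 lower, without replicate 3 they were 1901 and 1931, and without replicate 1 they were 4276 and 3881. Without moderation of the variance no gene passed in limma's fit, with 4903 at an unadjusted p under 0.05.

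Among the 10 named genes with the largest positive ratios, irg-5 (adjusted p = 0.000362, limma) was followed by pud-2.1 at 3.13 ± 0.58 and T16G12.3 at 2.99 ± 0.33 (SD, n = 3). The glucuronosyltransferase gene ugt-22 stood at 2.82 ± 0.24, the cuticle collagen gene col-101 at 2.78 ± 0.49 and pud-4 at 2.76 ± 0.84. Y38E10A.14, C27C7.1 and H11L12.1 stood at 2.72 ± 0.56, 2.63 ± 0.23 and 2.59 ± 0.24. The cytochrome P450 gene cyp-35C1 stood at 2.47 ± 0.08, with the smallest SD of the 10. Each was positive on all 3 arrays.

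Among the 10 with the largest negative ratios, acs-2 (adjusted p = 4.36e-05, limma) was followed by the cuticle gene rol-8 at -4.72 ± 0.27 and the alcohol dehydrogenase gene adh-1 at -4.58 ± 0.61 (SD, n = 3). The collagen genes col-36, col-158 and rol-6 stood at -4.22 ± 0.25, -4.04 ± 0.57 and -3.84 ± 0.56. The C-type lectin gene clec-60 stood at -4.19 ± 0.79 and the small heat shock protein gene hsp-12.6 at -4.08 ± 0.31. The fatty acid desaturase gene fat-3 stood at -3.85 ± 0.19 and C08E3.13 at -3.66 ± 0.32. Each was negative on all 3 arrays. Collagen genes are similar in sequence, so a probe of col-36, col-101 or col-158 may also take up transcripts of its relatives, and their values are uncertain to that extent.

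**Figure D1:**
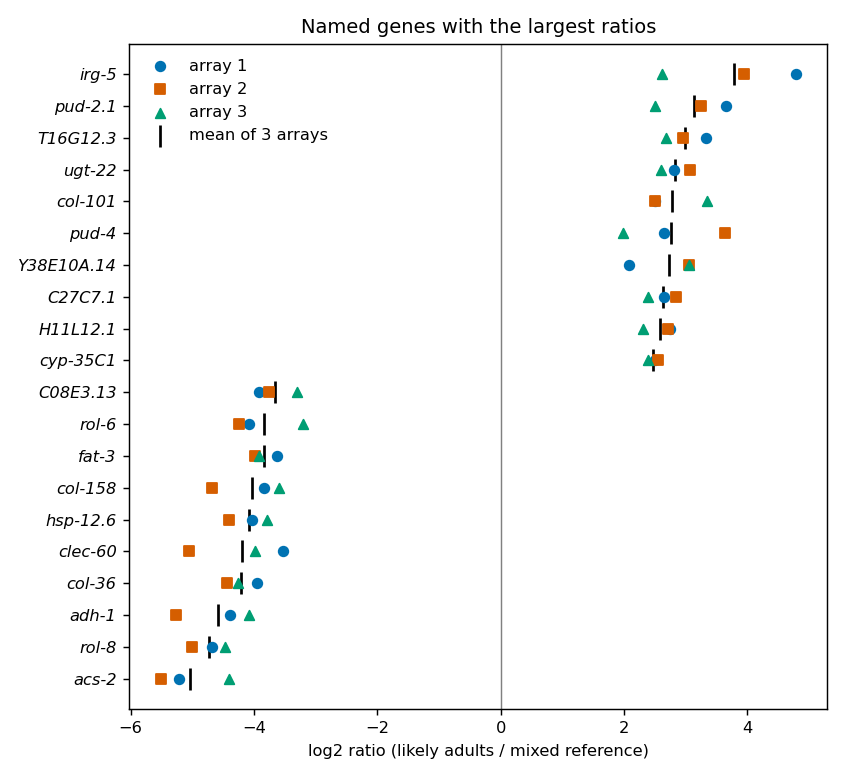
Log2 ratio (likely adults over mixed reference, horizontal axis) of the 10 named genes with the largest positive and the 10 with the largest negative mean ratios (vertical axis). Coloured points are the 3 arrays, numbered as the replicates, and the black tick is their mean, from 3.78 for irg-5 to -5.04 for acs-2, and every gene has the same sign on all 3 arrays.

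Most oocyte and eggshell genes were higher. Of 32 measured oocyte and maternal regulators, 29 were higher and 3 did not pass (29 when adjusted over the list alone), with a median log2 ratio of 1.19. The Pumilio-family RNA-binding protein genes puf-7 and puf-6 stood at 2.03 ± 0.14 and 1.99 ± 0.21, and rme-2, the yolk receptor gene, at 1.92 ± 0.09 (SD, n = 3). Of 13 eggshell and vitelline layer genes, 11 were higher and 2 did not pass (11 when adjusted over the list alone), with a median of 1.19. Among them cbd-1, a chitin-binding protein gene, stood at 1.92 ± 0.17, egg-4 at 1.81 ± 0.40 and egg-6 at 1.54 ± 0.17. In limma's camera test the adjusted p was 4.77e-17 for the oocyte list and 1.41e-07 for the eggshell list, and it was 0.283 for both with an estimated correlation. Of 3 measured vitellogenin genes, which encode yolk proteins, 1 was higher (1 when adjusted over the list alone). That gene was vit-2 at 0.99 ± 0.41 (adjusted p = 0.00526, limma), while vit-5 stood at 0.15 ± 0.17 (0.501) and vit-6 at 0.24 ± 0.74 (0.537). Without replicate 1 the value of vit-5 was 0.05, and with array weights it was 0.07. The value of vit-6 was -0.59 in replicate 1, 0.82 in replicate 2 and 0.49 in replicate 3. Without replicate 1 it was 0.66, with an adjusted p of 0.00508 (0.00508 to 0.937 over all alternatives), without replicate 2 it was -0.05 and without replicate 3 it was 0.11. With array weights it was 0.51 and passed (0.00683).

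Most germline chromosome genes and RNA regulators were higher as well. Of 36 P granule and germline RNA regulators, 27 were higher and 9 did not pass (27 when adjusted over the list alone), with a median of 0.94. The RNA helicase genes cgh-1 and glh-4 stood at 1.94 ± 0.22 and 1.82 ± 0.17, and the Argonaute gene wago-1 at 1.73 ± 0.15 (SD, n = 3). Of 29 meiotic chromosome genes, 23 were higher and 6 did not pass (26 when adjusted over the list alone), with a median of 0.81. The chromosome axis gene htp-3 stood at 1.06 ± 0.04, the helicase gene him-6 at 1.1 ± 0.18 and the nuclease gene mre-11 at 0.98 ± 0.08. Camera gave an adjusted p of 4.51e-13 for the P granule list and 3.74e-11 for the meiotic list, and 0.283 for both with an estimated correlation.

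Most replication, mitosis and proteasome genes were also higher. Of 47 DNA replication and mitotic cell cycle genes, 35 were higher and 12 did not pass (39 when adjusted over the list alone), with a median of 0.96. The B-type cyclin gene cyb-3 stood at 1.78 ± 0.12, the replicative helicase gene mcm-4 at 1.53 ± 0.12 and the centrosome gene spd-2 at 1.53 ± 0.17 (SD, n = 3). Of 29 proteasome genes, 23 were higher and 6 did not pass (26 when adjusted over the list alone), with a median of 0.78. The regulatory particle genes rpn-1, rpt-2 and rpn-5 stood at 1.41 ± 0.09, 1.16 ± 0.19 and 0.98 ± 0.12. Camera gave an adjusted p of 8.66e-16 for the replication list and 4.35e-11 for the proteasome list, and 0.283 for both with an estimated correlation. Of 55 histone genes, 4 were higher, 10 lower and 41 did not pass (3 and 7 when adjusted over the list alone), with a median of -0.04 and a camera adjusted p of 0.491. Among them his-1 stood at -0.90 ± 0.28, his-10 at -1.05 ± 0.47, his-26 at -0.74 ± 0.33 and his-47 at 0.90 ± 0.65. Histone genes occur in near-identical copies, so single members are uncertain. The histone counts without replicate 1 were 7 higher and 16 lower, and without replicate 2 or 3 they were 3 and 4. The value of his-47 was 1.65 in replicate 1, 0.54 in replicate 2 and 0.51 in replicate 3, and it was 0.53 without replicate 1 and 0.59 with array weights.

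Major sperm protein genes, which encode the cytoskeletal protein of nematode sperm, were mostly lower. Of 30 measured, 28 were lower and 2 did not pass (28 when adjusted over the list alone), with a median of -1.64. The medians of the arrays were -1.31, -2.24 and -1.40 for replicates 1, 2 and 3. Among them msp-33 stood at -2.42 ± 0.38, msp-59 at -2.39 ± 0.39 and msp-36 at -2.11 ± 0.25 (SD, n = 3). The camera adjusted p was 8.22e-18, and 0.327 with an estimated correlation. These genes are near-identical copies whose probes may share transcripts, so the 30 are not separate measurements. Of 33 other spermatogenesis genes, 2 were higher, 6 lower and 25 did not pass (2 and 6 when adjusted over the list alone), with a median of -0.15 and a camera adjusted p of 0.0987. Among them nspd-7 stood at -1.51 ± 0.52, ssp-16 at -1.18 ± 0.55 and spe-39, which also acts in vesicle traffic outside sperm, at 0.89 ± 0.15. Without replicate 1 the counts were 4 higher and 12 lower, and without replicate 2 they were 1 and 4. Without replicate 3 they were 1 and 7, with a camera adjusted p of 0.0462 (0.0462 to 0.415 over all alternatives). The list also passed with each of the 32 blocks of rows centred (0.0497, with 2 higher and 9 lower).

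Cuticle collagen and moulting genes held more lower than higher members, and many that did not pass. Of 152 cuticle collagen genes, 71 were lower, 17 higher and 64 did not pass (79 and 20 when adjusted over the list alone), with a median of -0.53. The ratios ran from -4.72 for rol-8 to 2.78 for col-101. Of 85 moulting and hedgehog-related genes, 33 were lower, 1 higher and 51 did not pass (34 and 1 when adjusted over the list alone), with a median of -0.33. The moulting counts without replicate 1 were 42 lower and 3 higher. Without replicate 2 they were 24 and 1, and without replicate 3 they were 25 and 1. The hedgehog-related genes grl-3, grl-23 and grl-9 stood at -2.42 ± 0.81, -1.89 ± 0.59 and -1.70 ± 0.10, and the patched-related gene ptr-2 at 1.35 ± 0.42 (SD, n = 3). Camera gave an adjusted p of 2.15e-08 for the collagens, and 0.537 with an estimated correlation. For the moulting list it gave 2.35e-07, and 0.283 with an estimated correlation. The adjusted p of fry, which asks whether a list's genes move on balance in 1 direction, was 0.123 for the collagens.

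Among neuronal genes 30 were lower and none higher, and muscle genes did not pass as a list. Of 61 neuronal genes, 30 were lower, 0 higher and 31 did not pass (34 and 0 when adjusted over the list alone), with a median of -0.55. The list holds 22 neuropeptide genes of the flp family, of which 17 were lower, so much of its count comes from 1 family. The medians of the list were -0.29, -0.73 and -0.68 on the arrays of replicates 1, 2 and 3. Without replicate 1 the counts of the list were 38 lower and 2 higher. Without replicate 2 they were 21 and 0, and without replicate 3 they were 24 and 0. The neuropeptide gene flp-1 stood at -3.17 ± 0.49, the synaptic vesicle release gene unc-13 at -1.59 ± 0.21 and the synaptotagmin gene snt-1 at -1.56 ± 0.18 (SD, n = 3). The camera adjusted p was 1.17e-08, and 0.327 with an estimated correlation. Of 39 muscle genes, 9 were lower, 3 higher and 27 did not pass (9 and 3 when adjusted over the list alone), with a median of -0.13 and a camera adjusted p of 0.240. The troponin genes tnc-2, tni-3 and pat-10 stood at -1.35 ± 0.50, -1.03 ± 0.23 and -0.88 ± 0.34, and the actin-depolymerising factor gene unc-60 at 0.69 ± 0.38. Without replicate 2 the muscle counts were 4 lower and 1 higher, and without replicate 3 they were 5 and 1.

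Intestinal and stress genes went both ways. Of 48 intestinal and digestive genes, 13 were higher, 17 lower and 18 did not pass (15 and 18 when adjusted over the list alone), with a median of -0.10 and a camera adjusted p of 0.272. Besides fat-3, dod-3 stood at -2.85 ± 0.33, the ferritin gene ftn-1 at -2.03 ± 0.29 and the acyl-CoA dehydrogenase gene acdh-1 at 1.79 ± 0.89 (SD, n = 3). The adjusted p of fry was 0.0332 in the lower direction for this list. The median of this list was -0.25 without replicate 1 and -0.06 without replicate 2, and without replicate 2 the counts were 7 higher and 14 lower. Of 29 heat shock and stress genes, 8 were higher, 4 lower and 17 did not pass (8 and 4 when adjusted over the list alone). The median of this list was 0.07, its mean was -0.13 and its camera adjusted p was 0.945. The small heat shock protein gene hsp-12.3 stood at -2.81 ± 0.11, the superoxide dismutase gene sod-4 at -1.50 ± 0.24 and the chaperone gene hsp-110 at 1.42 ± 0.31. Without replicate 3 the stress counts were 4 higher and 6 lower.

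The remaining lists did not pass. Of 27 early zygotic embryonic genes, 3 were higher, 3 lower and 21 did not pass (3 and 2 when adjusted over the list alone), with a median of -0.05 and a camera adjusted p of 0.648. The lowest was nhr-57, a nuclear hormone receptor gene known as a target of the hypoxia response, at -1.91 ± 0.11 (SD, n = 3), and hch-1 stood at 0.57 ± 0.06 and med-1 at -0.62 ± 0.30. Leaving out replicate 1 gave 6 higher and 5 lower. Without replicate 2 or 3 they were 0 and 1, and neither hch-1 nor med-1 passed. Of 14 somatic gonad genes, 3 were higher, 1 lower and 10 did not pass (4 and 1 when adjusted over the list alone), with a median of 0.13 and a camera adjusted p of 0.524. Its member with the smallest p was inx-14, known as a germline innexin gene, at 0.99 ± 0.04, and cog-1 stood at 0.63 ± 0.25 and ceh-18 at -0.88 ± 0.57. Without replicate 1 the counts were 3 higher and 2 lower. Without replicate 2 they were 4 and 0, and ceh-18 did not pass. Without replicate 3 they were 2 and 1, and cog-1 did not pass. With each of the 32 blocks of rows centred cog-1 stood at 0.41, and with the neighbourhood median subtracted at 0.37. Of 15 genes of male-specific neurons and seminal fluid, 1 was lower and 14 did not pass (1 when adjusted over the list alone), with a median of -0.03 and a camera adjusted p of 0.624. The protease inhibitor gene swm-1 stood at -1.13 ± 0.22, and try-5 and lov-1, which did not pass, at -0.57 ± 0.58 and 0.29 ± 0.15. The values of try-5 were -1.24, -0.26 and -0.23 in replicates 1, 2 and 3. Without replicate 1 its mean was -0.24, and with array weights it was -0.30. Without replicate 2 or 3 it was -0.73 or -0.75 and passed, which made 2 lower (adjusted p 0.0344 to 0.411 over all alternatives, limma). The value of lov-1 is the mean of 2 rows, which stood at 0.00 and 0.58 when not averaged, and only the second passed (adjusted p = 0.0211, limma, with 0.0211 to 0.989 over all alternatives). With array weights lov-1 passed at 0.27 (0.0489), and it was 0.12 with the blocks of rows centred and 0.17 with the neighbourhood median subtracted.

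Of 63 ribosomal protein genes, 2 were higher, 4 lower and 57 did not pass (2 and 2 when adjusted over the list alone). The median was 0.03 and the mean 0.01, and camera, at an adjusted p of 0.945, pointed to the lower side. Among them rpl-11.1 stood at 0.96 ± 0.21, rpl-23A.2 at 0.66 ± 0.13 and rpl-23A.1 at -1.0 ± 0.36 (SD, n = 3), and rpl-23A.2 did not pass without replicate 2 or 3. Without replicate 1 the counts were 2 higher and 9 lower, without replicate 2 or 3 they were 1 and 2, and with array weights they were 10 and 10. With the blocks of rows centred they were 2 and 8, and with the neighbourhood median subtracted they were 3 and 10. Of 33 genes of the mitochondrial respiratory chain and ATP synthase, 5 were higher, 5 lower and 23 did not pass (5 and 5 when adjusted over the list alone), with a median of -0.16 and a camera adjusted p of 0.332. Among them ucr-2.3 stood at 0.91 ± 0.19, ucr-2.1 at -0.93 ± 0.24 and asg-2 at -0.93 ± 0.34. Counts of this list without replicate 1 were 5 higher and 11 lower, without replicate 2 they were 4 and 3, and without replicate 3 they were 3 and 3. Of 15 glycolysis genes, 4 were higher, 3 lower and 8 did not pass (4 and 4 when adjusted over the list alone), with a median of -0.01 and a camera adjusted p of 0.945. The dehydrogenase gene gpd-4 stood at 0.95 ± 0.16, the isomerase gene tpi-1 at -0.95 ± 0.16 and the aldolase gene aldo-1 at -1.18 ± 0.48. Without replicate 1 the counts were 5 higher and 5 lower, without replicate 2 they were 3 and 2, and without replicate 3 they were 2 and 2.

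Of the 21 lists with at least 5 measured members, 10 passed camera's preset correlation at an adjusted p of 0.05, 6 of them higher and 4 lower. With an estimated correlation 0 passed. The unadjusted camera p with an estimated correlation was 0.0301 for the oocyte list and 0.0411 for the proteasome list. It was above 0.05 for every other list. In fry 10 lists passed in 1 direction and 21 for change in either direction. The medians of the lists that did not pass ran from -0.16 to 0.13. That of the somatic gonad list was 0.09 to 0.18 with a replicate left out, and those of the other lists moved by more than 1.5 times or changed sign in at least 1 such fit. Without replicate 1 the median of the early zygotic list was 0.02, of histones -0.08, of ribosomal proteins -0.02, of glycolysis -0.08 and of stress genes -0.02. Without replicate 2 it was -0.12 for early zygotic genes, -0.10 for other spermatogenesis genes, -0.05 for muscle, 0.09 for ribosomal proteins, -0.09 for mitochondrial genes and 0.13 for glycolysis. Without replicate 3 it was -0.08 for early zygotic genes, 0.01 for male-specific genes, 0.01 for ribosomal proteins and 0.04 for glycolysis. With the blocks of rows centred or the neighbourhood median subtracted, the median was -0.06 or -0.07 for ribosomal proteins and 0.05 or 0.03 for male-specific genes. With array weights it was 0.02 for early zygotic genes, -0.02 for muscle, -0.07 for mitochondrial genes and -0.01 for stress genes.

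With array weights more members of most lists passed. The counts were then 8 higher and 6 lower for early zygotic genes, 5 and 14 for other spermatogenesis genes, 8 and 18 for histones, 27 and 77 for cuticle collagens, 3 and 43 for moulting genes, 6 and 14 for muscle and 2 and 39 for neurons. For the somatic gonad they were 4 and 3, for male-specific genes 1 and 1, for mitochondrial genes 6 and 11, for glycolysis 5 and 5 and for stress genes 12 and 6. Without replicate 1 or with array weights 1 eggshell gene was lower. Higher members without replicates 1, 2 and 3 in turn were 30, 26 and 27 for oocyte genes and 11, 11 and 11 for eggshell genes. For meiotic genes they were 27, 19 and 21, and for P granule genes 33, 23 and 23. For replication genes they were 39, 28 and 33, and for the proteasome 26, 22 and 18. With the blocks of rows centred or the neighbourhood median subtracted, the counts were 4 and 5 for early zygotic genes, 5 and 11 for mitochondrial genes and 4 and 2 for the somatic gonad, and 2 moulting genes were higher. With the neighbourhood median subtracted they were 5 and 5 for glycolysis, and 1 neuronal gene was higher.

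**Figure D2:**
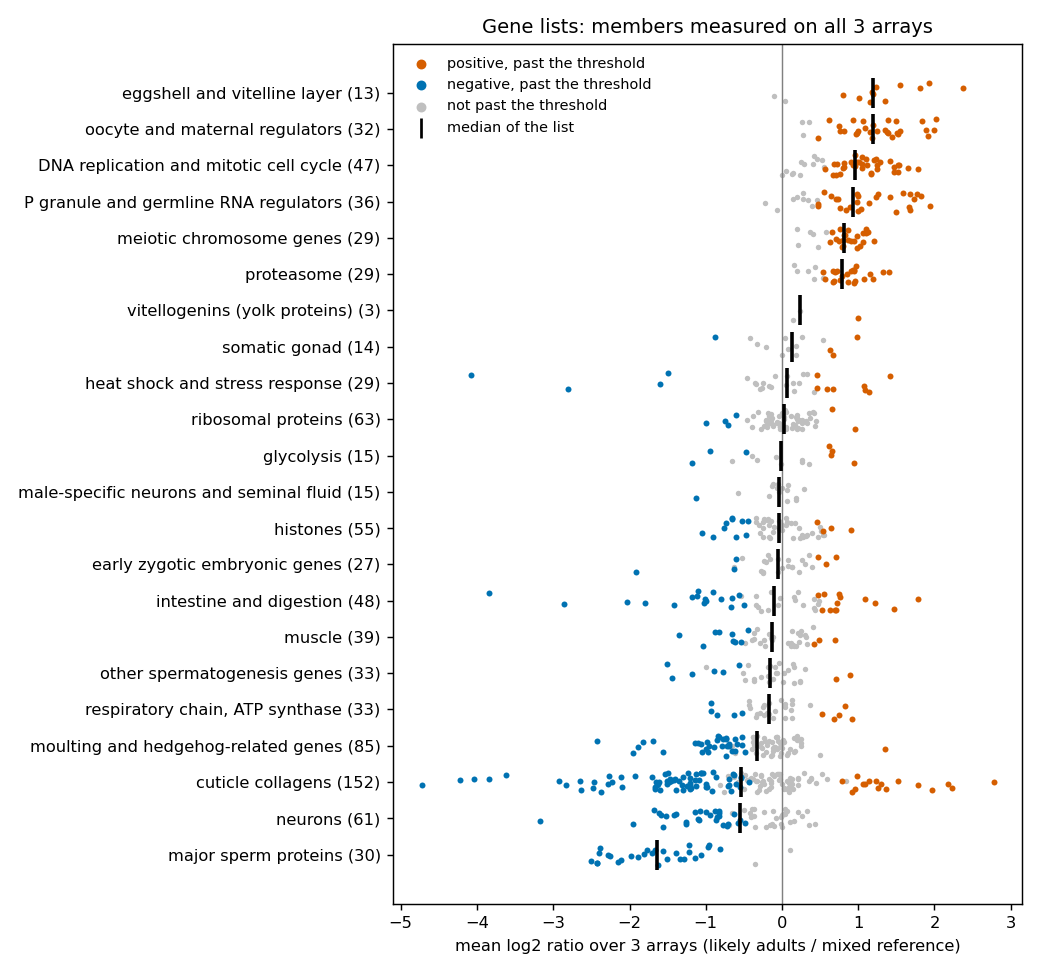
Mean log2 ratio over 3 arrays (likely adults over mixed reference, horizontal axis) of each measured member of the 22 gene lists (vertical axis, number of members in brackets). Coloured points passed the adjusted p in limma, grey points did not and black ticks are list medians, which run from -1.64 for major sperm proteins to 1.19 for eggshell genes.

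The arrays differed in how closely they matched. Across 19293 genes, which are not independent replicates, replicates 2 and 3 correlated at a Pearson r of 0.895 (Spearman 0.841). Replicate 1 correlated at 0.686 (0.568) with replicate 2 and at 0.679 (0.568) with replicate 3. The difference of replicate 1 from the mean of the others changed with the row's place in the table, when rows were laid out as 32 blocks of 25 by 25, 4 across and 8 down. Block medians of that difference ran from -0.469 to 0.482, against -0.114 to 0.133 for replicate 2 minus replicate 3. This layout was inferred from periods in the values and is not given in the labels. With the median of an 11 by 11 neighbourhood subtracted, 3303 genes were higher and 3535 lower, of which 2668 and 2589 were among the 2854 and 2647 called on the values as deposited.

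**Figure D3:**
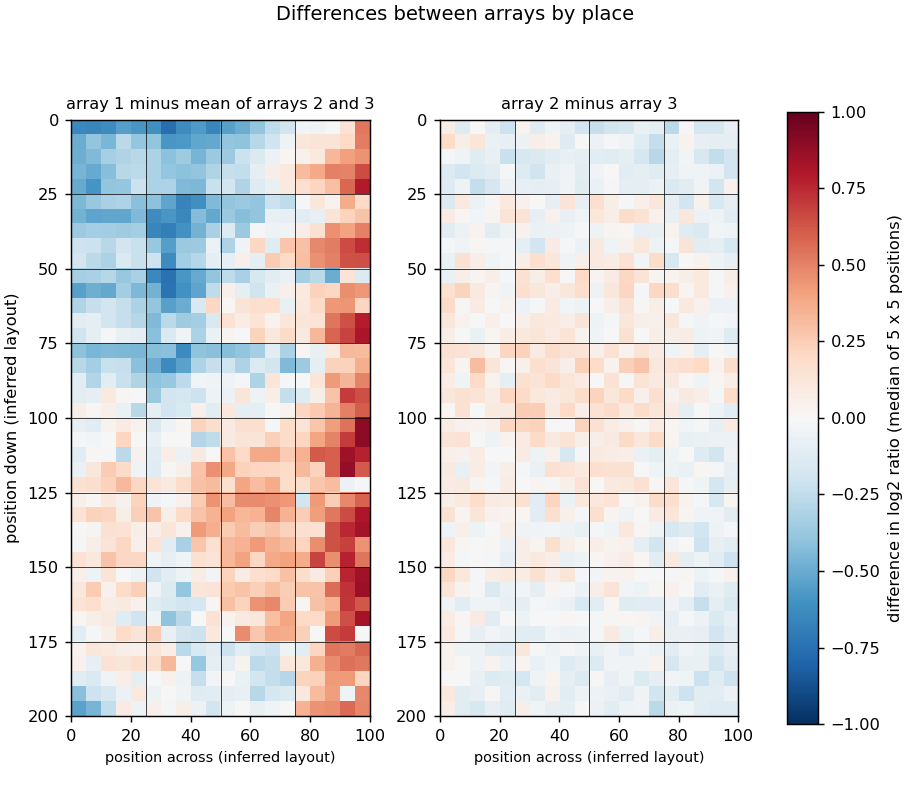
Difference in log2 ratio between arrays (colour, median of 5 by 5 positions) by place across and down a layout inferred from the table's row order, with lines between blocks of 25 by 25. Replicate 1 minus the mean of replicates 2 and 3 (left) has block medians from -0.469 to 0.482, and replicate 2 minus replicate 3 (right) from -0.114 to 0.133.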

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

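The place corrections and the list medians without each replicate were chosen after the data were seen. Of 1034 values of named genes under the alternatives, 937 kept their direction and side of the threshold, 90 lost the threshold, 6 gained it and 1 reversed. Of 273 list values, 258 kept both, 10 lost the threshold, all with an estimated correlation, 2 gained it and 3 reversed. The counts of 2854 higher and 2647 lower genes became 4874 and 4413 with array weights (0.282, 1.12 and 3.16 for replicates 1, 2 and 3). They were 1511 and 1444 at an adjusted p under 0.01, and 749 and 941 with an absolute log2 ratio of at least 1, both stricter by construction. Without moderation limma called 0 and 0, with 4903 genes at an unadjusted p under 0.05. Leaving out each replicate gave 1796 to 4276 higher and 1687 to 3881 lower genes. Of the 2854 and 2647, 2829 and 2626 were kept without replicate 1, 1729 and 1630 without replicate 2, and 1813 and 1843 without replicate 3. The 6 higher and 4 lower lists became 0 and 0 with an estimated correlation. The median of vitellogenins was 0.19 to 0.66 with a replicate left out, and that of moulting genes was -0.26 with the 11 by 11 neighbourhood median subtracted. Reversed values were those of vit-6, -0.0491 without replicate 2 (-0.0491 to 0.66 over replicates left out, adjusted p 0.00508 to 0.937 over all alternatives), and of 3 lists that passed under no alternative. These were ribosomal proteins (-0.0197 to 0.0941), glycolysis (-0.0819 to 0.13) and heat shock and stress (-0.0182 to 0.0834), as medians with a replicate left out, and camera's direction turned without replicate 2 for the first and second and without replicate 3 for the last. Except where stated, the cause was not tested. No paired analysis was possible because the series holds 1 group. Signal over background is not known here, so limits from dim spots could not be assessed.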

Other observations

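The gene classes, the added fasting and dauer genes and the gene pairs below were chosen after the data were seen. The tests of place as a source of the difference of replicate 1 and of a lower share of somatic RNA were also chosen only after those results were seen.

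In a scan of 149 symbol classes with at least 10 measured members, 21 classes were higher and 31 lower in limma's camera test, and 0 passed with an estimated correlation. Of 52 neuropeptide-like nlp genes, 34 were lower and 0 higher, with a median log2 ratio of -0.97 (adjusted p = 2.74e-13, and 0.520 with an estimated correlation), led by nlp-17 at -2.55 and nlp-47 at -2.35. Of 22 FMRFamide-related flp genes, which are part of the neuronal list, 17 were lower, with a median of -0.93 (5.24e-09, and 0.520). Of 46 transthyretin-related ttr genes, 24 were lower and 1 higher, with a median of -0.50 (9.96e-07, and 0.520). Of 237 nuclear hormone receptor nhr genes, 53 were lower and 2 higher, with a median of -0.12 (0.00110, and 0.520). Without replicate 1 these nhr counts were 80 and 11, without replicate 2 they were 33 and 1, without replicate 3 they were 35 and 0, and with array weights they were 95 and 18. The ttr counts were 14 and 1 without replicate 2, 26 and 2 without replicate 1, and 25 and 4 with array weights. Of 173 srh and 165 str genes, both classes of chemoreceptor genes, 1 and 0 were higher and 1 and 1 lower, and neither class passed. Without replicate 1, 4 srh genes were higher and 6 lower, and 3 str genes were higher and 6 lower. With array weights these counts were 7 and 12 for srh and 5 and 9 for str. Without replicate 2 they were 0 and 1 for srh and 0 and 0 for str, and without replicate 3 they were 1 and 2 and 0 and 0. Of 26 srlf genes 11 were lower and 0 higher, with a median of -0.43 (0.00320, and 0.662 with an estimated correlation), and without replicate 2 the median was -0.27. Without replicate 1 or with array weights 1 srlf gene was higher.

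Of 21 nuclear pore npp genes, 19 were higher and 0 lower, with a median of 0.91 (adjusted p = 5.24e-09, and 0.520 with an estimated correlation), led by npp-9 at 1.55 and npp-10 at 1.62. Of 11 pre-mRNA processing prp genes, 10 were higher, with a median of 0.73 (0.000442, and 0.520), and of 19 translation initiation eif genes 13 were higher, with a median of 0.68 (0.000839, and 0.520). Of 24 set genes, named for a domain of histone methyltransferases, 13 were higher and 1 lower, with a median of 0.55 (0.00110, and 0.520). Without replicate 2 or 3 the higher genes were 4 or 5 for prp and 7 or 8 for eif, and 0 set genes were lower with 9 or 10 higher. Without replicate 1 or with array weights 2 set genes were lower, and with array weights 1 eif gene was lower. Some pairs of related genes were singled out because they stood on opposite sides, and pairs were not counted or tested as a group. The ATP synthase genes asb-1 and asb-2 were at 0.82 and -0.85, asg-1 and asg-2 at 0.53 and -0.93, and the ribosomal protein genes rpl-11.1 and rpl-11.2 at 0.96 and -0.71, all 6 past the threshold in limma. Without replicate 2 or 3, asg-1 and rpl-11.2 did not pass.

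Genes known from fasting or dauer, the arrested larval stage, were among the most negative, including acs-2 and hsp-12.6. A hypothesis is that the mixed reference held fasting or dauer animals. Of 30 other genes known from fasting or dauer, written down before their values were looked up, 26 were measured, with a median of -0.93. Of these, 15 were lower and 0 higher (20 and 1 without replicate 1 or with array weights), and 6 were also in another list. The camera p was 9.24e-08, and 0.216 with an estimated correlation. Lower members included aqp-1 at -2.41, icl-1 at -1.92 and tps-1 at -1.17. The other members did not pass on all 3 arrays, among them sod-3 at -0.17, ctl-2 at -0.09, lbp-1 at 0.04 and lea-1 at 0.33. After the neighbourhood median was subtracted, the 10 most negative named genes kept at least 97.6% of their ratio. Block medians of the difference of replicate 1 ran only from -0.469 to 0.482, so ratios this large could lose little. The check shows only that a smooth bias over the inferred layout was small beside these ratios. The 20 genes in no other list lay below the muscle median by a difference of -0.866 (95% bootstrap interval over genes -1.36 to -0.223). The difference was -0.894 (-1.51 to -0.162) for the intestine and -0.444 (-0.860 to 0.250) for neurons, where the interval included 0. A lower share of somatic RNA in the adults would lower somatic lists alike. The list medians were -0.13 for muscle, -0.10 for intestine and -0.55 for neurons, so this comparison cannot decide on it. Fasting or dauer animals in the reference stay a hypothesis, since the list was drawn up after the most negative genes were seen. The list also did not pass camera with an estimated correlation (p = 0.216). A difference between adults and larvae in general was not tested and stays open.

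Replicate 1 differed from replicates 2 and 3. A bias that follows place on the array stays open as a part of this. The deviation of replicate 1 correlated at 0.411 between rows 25 apart, against 0.303 and 0.297 at 12 and 13 apart. For replicate 2 minus replicate 3 the correlation at 25 apart was 0.0614. The layout was inferred from such periods in the same values, so the period of 25 cannot decide on place. Between adjacent rows, which needs no layout, the correlation was 0.455 for replicate 1 and 0.103 for replicate 2 minus replicate 3. The deviation of replicate 1 thus followed row order, but how row order maps to the array is not known. A smooth bias over the inferred layout is argued against as the whole of the difference of replicate 1. With the neighbourhood median subtracted, the mean correlation of replicate 1 with the others went from 0.682 to 0.770. That was below the 0.897 between replicates 2 and 3 by 0.126 (95% interval 0.0976 to 0.162 over 1000 block bootstrap draws). Another germline content of preparation 1 also stays open: over 144 germline genes the median deviation after that subtraction was 0.0206 (interval -0.0800 to 0.0857), inside a bound set before the test, but 73 genes lay above 0 and 71 below, and the bound was set without a size of shift that the explanation would need. Each preparation was hybridised on 1 array, and no other biological explanation was tested.

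With the sign of 1 array turned, 1 of 4 sign patterns, the real one, gave as many as the real 5501 genes past the threshold, and the highest other count was 0. The 4 patterns are too few for a share under 0.05. The arrays correlated at 0.679 to 0.895, so turning 1 of them makes changed genes disagree between arrays. A low count was therefore bound to follow, and the contrast decides nothing.

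Sperm genes other than major sperm proteins had a median of -0.15, against -1.64 for major sperm proteins, and the difference between the lists was not tested. Among rows without a single gene name, 2 had a larger mean than irg-5, both at 4.54.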
